A study of Mus musculus with 6 samples.

How the data were processed

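The series holds RNA sequencing of lymphatic endothelial cells, the cells that line lymphatic vessels, sorted from the meninges (the membranes around the brain) of male C57BL/6 mice. Per the labels, cells negative for CD45 (a leukocyte surface protein) and positive for CD31 (an endothelial protein encoded by Pecam1) and for podoplanin (encoded by Pdpn) were collected by flow cytometry. There were 3 samples from young mice aged 2 to 3 months and 3 samples from old mice aged 20 to 24 months. Total RNA was extracted with a kit for small samples, amplified linearly and sequenced by a service laboratory, per the labels' protocols. The young and old mice came from a commercial breeder or from the US National Institute on Aging and were kept under the same housing conditions. Which sample came from which source is not given in the sources used here. Nothing states that the 3 samples of a group were separate animals or pools, so p-values measure only the spread between these samples, which may be technical.

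The submitters' processing notes name FastQC, Salmon and the mouse build mm10, with no versions and no role for each. The table used here holds estimated counts per gene as deposited by the authors. The estimated counts were already whole numbers, so rounding changed nothing. The 8 largest-scale values, those with at least 7 digits, were all multiples of 10, and the smallest total of a gene over the 6 samples was 2. The gene annotation, the step from transcripts to genes and the rounding are not given in the sources used here. Salmon spreads reads that match several transcripts by likelihood, so estimates for genes with near-identical copies depend on that split. These genes are reported as uncertain. Strandedness is likewise not given in the sources used here.

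Of 22964 genes in the table, identified by Ensembl gene identifiers, 22738 had a symbol in the GENCODE M21 annotation of GRCm38, the assembly that mm10 denotes. Gene positions come from that annotation and are 1-based. Groups were taken from the labels. The depth was 14285794 to 21043945 estimated counts per sample.

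Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with its default minimum of 10 counts and minimum total of 15, TMM factors, a robust quasi-likelihood fit on age group with no covariate, and a two-sided quasi-likelihood test. P-values were adjusted by Benjamini-Hochberg at a threshold of 0.05. The filter left 15394 genes and removed 7570. Log2 fold changes are old against young with their standard errors. Levels are given in CPM, the deposited estimated counts scaled to the TMM-adjusted library size, as mean ± SD over the 3 samples of a group. Log2 CPM used a prior count of 2.

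Gene lists were tested with camera from limma 3.58.1 on the edgeR object, with the correlation between genes preset at 0.01 and Benjamini-Hochberg adjustment over 33 lists of at least 5 tested members. Camera asks whether the members of a list stand apart from the other genes. Of the 34 lists written, 22 describe endothelial biology, metabolism and stress and the others are markers of cell types that the sort or the dissected tissue could hold. The list of muscle, bone and cartilage markers kept too few tested members, which were Alpl, Dmp1 and Acan, and was not tested. A list's score in a sample is the mean log2 CPM of its members. Calls among a list's members were also counted after adjustment over the list alone.

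The groups, the design, the gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined, except where a choice is said to have been made later. By that rule, Prox1, Lyve1, Pdpn, Pecam1, Flt4, Ccl21a and Ptprc were always named. Up to 12 genes per direction were to be named among genes past the threshold whose groups did not overlap and whose mean was at least 5 CPM, without predicted or unnamed loci. From each list, up to 4 members past the threshold were to be named. From a called list with fewer than 2 such members, the 2 members with the smallest p were named as values. Some genes that the rule names are not reported here. Other genes in the text are members of the lists or are said to have been chosen after their values were seen.

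The gene tests and the list test were checked on simulated counts drawn for these genes and samples. Each simulation was drawn once, with the spread of each gene as edgeR estimated it. With 200 genes changed among all 15394, edgeR recovered 0% of those changed 2-fold, 6.25% of those changed 4-fold and 22.6% of those changed 8-fold, and 2 of its 20 calls were false. With the changed genes drawn from those of at least 50 CPM, the shares were 0%, 26.5% and 82.2%, and 4 of 77 calls were false. DESeq2 made 98 false calls among 150 and 109 among 201 in the same simulations. The limma-voom test made 1 false call among 15 and 0 among 59. In a simulation of 20 lists of 25 genes, of which 5 were shifted 2-fold, camera called all 5 shifted lists and 0 of the others, with the preset and with an estimated correlation. The simulated genes were drawn independently of each other, so this did not check the preset for lists of correlated genes.

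The alternatives were median-ratio size factors, library size without a composition factor, no filter, a minimum mean of 50 counts, DESeq2 1.42.0, limma-voom, limma-voom with sample weights, a fit without robust estimation, a test against a fold of 1.5, the replicate number as a block, 1 surrogate variable from sva 3.50.0, and leaving out each sample in turn. Lists were also tested with an estimated correlation, with fry, and without the member with the smallest p. Alternatives chosen after seeing the data were a minimum mean of 500 counts, the edgeR likelihood ratio test, lists without members shared between lists, and variants of the DESeq2 fit. Adjusted p-values that DESeq2 gave as NA were left as NA. No sample was left out of the comparison of age groups.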

Results

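The series profiled the messenger RNA of meningeal lymphatic endothelial cells, which line the vessels that drain fluid and cells from the membranes around the brain, in young and old male mice. It forms 1 part of a study of meningeal lymphatic vessels in ageing and Alzheimer's disease. The comparison was between 3 samples of cells from mice aged 2 to 3 months and 3 samples from mice aged 20 to 24 months. The estimated counts summed to 15733100, 18673806 and 21043945 in the young samples and to 14803269, 14285794 and 20886836 in the old samples. Between 17074 and 18949 genes had a count in a sample. Mitochondrial ribosomal RNA took 16.52%, 15.65% and 15.98% of the counts in the young samples and 20.17%, 21.89% and 16.04% in the old samples. Over genes, Pearson correlations of log2 CPM were 0.679 to 0.814 between samples of the same age and 0.692 to 0.788 between samples of different age. The first principal component, with 30.9% of the variance, set old sample 1 apart, and the second, with 22.6%, set old sample 3 apart. No 2 samples were the same library, since the smallest chi-square per degree of freedom between any pair was 114.

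Transcripts of lymphatic endothelium were present in all 6 samples, together with transcripts of other cell types. Levels are given as mean ± SD in CPM over 3 samples per group. Prox1 (ENSMUSG00000010175; chromosome 1, 190118035 to 190170714, minus strand, in GRCm38), the transcription factor that sets lymphatic endothelial fate, had 909 ± 34.4 CPM in young and 1112 ± 259 CPM in old cells. Lyve1, a hyaluronan receptor of lymphatic endothelium, had 1149 ± 168 and 1483 ± 95.2 CPM. Pecam1, which encodes CD31, had 374 ± 46.5 and 611 ± 107 CPM, and Pdpn, which encodes podoplanin, had 72.2 ± 9.22 and 93.8 ± 43.4 CPM. Ptprc, which encodes the CD45 protein selected against, had 0.993, 57.4 and 72.7 CPM in young samples 1, 2 and 3 and 31.0, 30.7 and 62.9 CPM in old samples 1, 2 and 3. Pdpn had 61.9, 75.1 and 79.7 CPM in those young samples and 57.8, 142 and 81.6 CPM in those old samples. Col1a2, a collagen gene of fibroblasts, had 1983 ± 525 and 667 ± 93.5 CPM. None of these genes passed the edgeR test over all genes.

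In old cells, interferon-stimulated genes, antigen processing and presentation genes, lymphatic identity genes and endothelial junction genes rose as lists, and fibroblast markers, extracellular matrix genes and macrophage markers fell. Of the 33 lists tested, 13 were called by camera, 10 higher and 3 lower in old cells. With an estimated correlation the interferon list alone kept its call, as it did by fry. None of the 13 changed direction under any scaling, filter or test tried. The scores of 8 lists did not overlap between the ages, where chance gives 10% for any single list. An exact permutation test of 3 samples against 3 cannot give a p below 0.1. Single genes did not pass: edgeR called 0 of 15394 genes after adjustment, with a smallest adjusted p = 0.235. At an unadjusted p under 0.05, which a share of 0.05 of unchanged genes would reach, it counted 856 genes, 441 higher and 415 lower. A split of the samples that mixed the ages gave 869. With library size as the only scaling it counted 285 higher and 546 lower, as the median of all genes moved from 0.02 to −0.12 log2 units. The counts were 425 higher and 718 lower with 1 surrogate variable, and 564 higher and 832 lower without old sample 2. DESeq2 called 130 genes, 66 higher and 64 lower. Limma-voom called 3, which were Ccl21a, its copy Gm21541 and Sparc. The common biological coefficient of variation was 90.1%, and its median over genes ran from 118% under 3 CPM to 31.0% at 300 CPM or more.

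**Figure D1:**
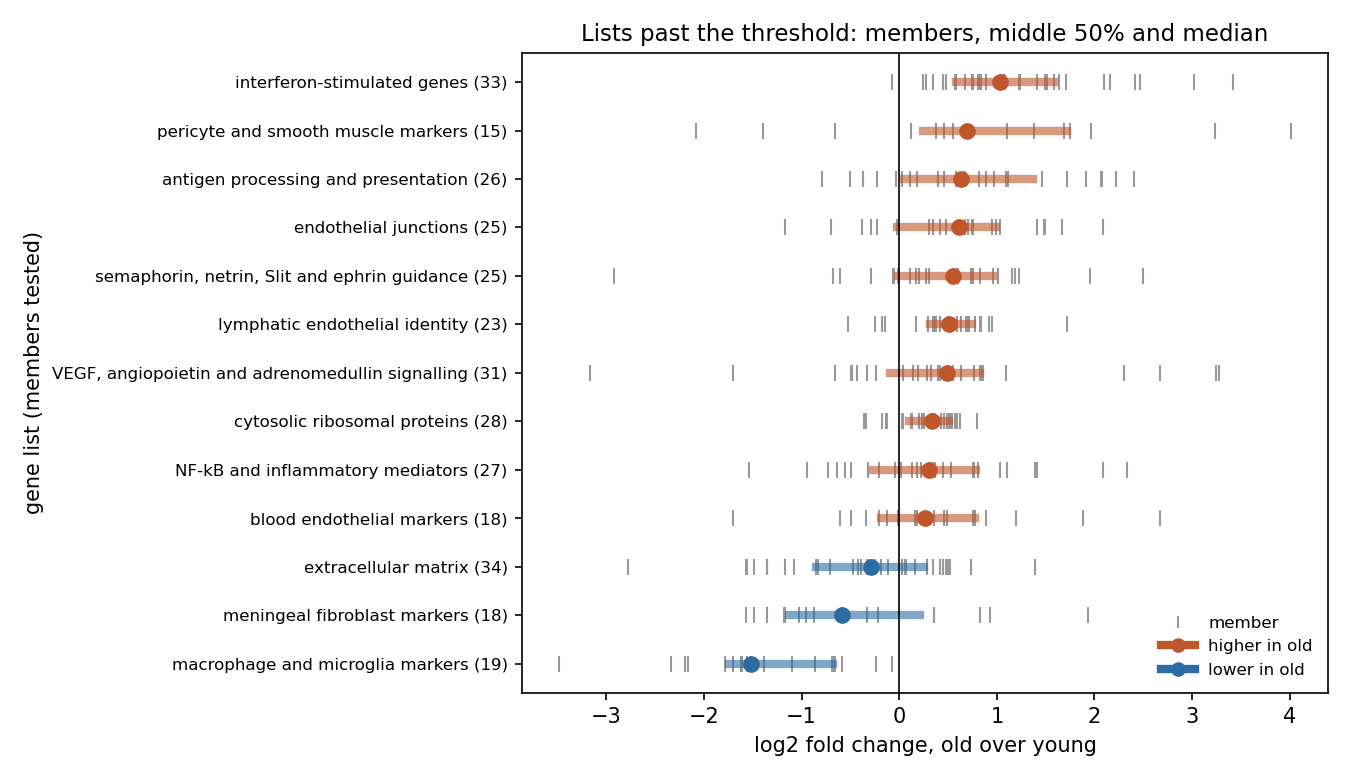
Log2 fold change, old against young, of the members of the 13 lists called by camera; grey ticks are members, the thick bar spans the 25th to 75th percentile, the dot is the median (orange, higher in old; blue, lower), and the number of members tested is in brackets. The interferon-stimulated list has a median of 1.04, and the macrophage list has a median of −1.52 with a wide spread of members.

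Interferon-stimulated genes, which encode antiviral and signalling proteins that cells make in response to interferons, rose most clearly. Of 33 members, 32 had a positive log2 fold change, with Xaf1 the exception. The median was 1.04, or 2.05-fold, with an interquartile range of 0.58 to 1.58. The list score went from 4.35 ± 0.43 to 5.54 ± 0.13 on the log2 CPM scale, with every old sample above every young one. Adjusted over the list alone, 8 members passed in edgeR: Ifi27l2a, Ifitm3, Oas1a, Ifi44, Ddx60, Irf9, Rsad2 and Zbp1, each with adjusted p = 0.044. Ifitm3 (chromosome 7, 141009586 to 141010770, minus strand), a membrane protein that restricts virus entry, had 417 ± 26.6 CPM in young and 728 ± 121 CPM in old cells. Irf9, a subunit of the transcription factor that carries the type I interferon signal, had 58.9 ± 30.6 and 156 ± 24.5 CPM, and Zbp1, a sensor of nucleic acids, had 26.6 ± 16.5 and 86.8 ± 8.54 CPM. Ifi27l2a, a mitochondrial protein induced by interferon, had 16.1 ± 2.00 and 71.7 ± 17.9 CPM and is uncertain because of near-identical copies. The scatter was wide for Oas1a, another member with such copies, at 5.72 ± 3.74 and 61.1 ± 60.9 CPM. Irf7, the master regulator of type I interferon genes, had 5.94 ± 7.33 and 48.1 ± 15.4 CPM without passing. Camera gave the list an adjusted p = 1.4e-13, which was 0.0443 with an estimated correlation, and fry gave an adjusted p = 0.0394.

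Antigen processing and presentation genes rose with a median of 0.63 over 26 members, of which 20 were positive. H2-Q7, H2-K1, B2m and H2-D1, which encode parts of class I molecules, were the 4 members that passed adjusted over the list alone, with edgeR adjusted p = 0.00064, 0.0015, 0.0015 and 0.004. B2m (chromosome 2, 122147686 to 122153083, plus strand), the light chain shared by class I molecules, went from 948 ± 45.5 to 1865 ± 181 CPM, a log2 fold change of 0.98 (SE 0.16). The heavy chain gene H2-K1 (chromosome 17, 33996017 to 34000347, minus strand) went from 267.8 ± 15.001 to 882 ± 288 CPM, and H2-D1 (chromosome 17, 35262730 to 35267499, plus strand) from 373 ± 39.6 to 808 ± 151 CPM. H2-Q7 (chromosome 17, 35439155 to 35443773, plus strand), a nonclassical class I gene, went from 74.6 ± 20.2 to 396 ± 63.9 CPM, a log2 fold change of 2.41 (SE 0.30). The H2 genes have near-identical copies, so the split of reads among them is uncertain. B2m is not among them. Cd74, the class II invariant chain, had 429 ± 213 and 464 ± 101 CPM and did not pass. The list score went from 5.70 ± 0.36 to 6.38 ± 0.25, with adjusted p = 2.6e-06 by camera and adjusted p = 0.149 with an estimated correlation. Over all genes, edgeR gave B2m, H2-K1 and H2-Q7 no call, while DESeq2 gave adjusted p = 0.021, 0.00051 and 2.1e-08. The 41 leukocyte markers tested had a median log2 fold change of −0.56, with an interquartile range of −1.56 to 0.44. Of these, the macrophage list had a median of −1.52, the lymphocyte and plasma cell list 0.42 and the granulocyte and mast cell list 0.77.

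Lymphatic endothelial identity genes rose by a median log2 fold change of 0.51, with 19 of 23 members positive and an interquartile range of 0.32 to 0.74. Ccl21a (ENSMUSG00000094686; chromosome 4, 42772860 to 42773993, minus strand), the chemokine that guides dendritic cells and T cells into lymphatic vessels, had 2728 ± 342 CPM in young and 5277 ± 714 CPM in old cells, a log2 fold change of 0.95 (SE 0.16). Adjusted over the list alone, edgeR gave it an adjusted p = 0.0049, and over all genes 0.300. The estimates for Ccl21a are uncertain because 6 loci of near-identical sequence on chromosome 4 share its reads. Their sum went from 4218 ± 654 to 8141 ± 1281 CPM, a ratio of 1.93. Mmrn1, a secreted multimerin of lymphatic endothelium, went from 2026 ± 265 to 3288 ± 408 CPM, Nrp2, a co-receptor for VEGF-C, from 798 ± 132 to 1428 ± 315 CPM, and Reln, a secreted glycoprotein of collecting lymphatics, from 1758 ± 413 to 2889 ± 400 CPM. These 3 passed adjusted over the list alone at adjusted p = 0.024, 0.029 and 0.037. Flt4, the receptor for VEGF-C also called VEGFR3, had 2001 ± 310 and 2823 ± 208 CPM, a log2 fold change of 0.50 (SE 0.16), and did not pass. The list score went from 7.80 ± 0.23 to 8.36 ± 0.12 with no overlap. Camera gave adjusted p = 1.7e-06, and adjusted p = 0.149 with an estimated correlation.

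Endothelial junction genes rose as a list, with 18 of 25 members positive, a median of 0.61 and a score of 5.84 ± 0.18 in young and 6.38 ± 0.15 in old cells. Ctnnb1, which encodes beta-catenin at adherens junctions, went from 209 ± 26.3 to 428 ± 64.2 CPM and was the 1 member that passed adjusted over the list alone, at edgeR adjusted p = 0.045. Cldn5, a claudin of endothelial tight junctions, had 76.3 ± 17.7 and 213 ± 88.6 CPM. Camera gave adjusted p = 0.000108, and adjusted p = 0.149 with an estimated correlation. Guidance genes of the semaphorin, netrin, Slit and ephrin families had 18 of 25 members positive and a median of 0.55. Ntn1, a netrin, had 101 ± 17.3 and 230 ± 27.5 CPM, and Sema3f, a semaphorin that binds Nrp2, had 15.6 ± 6.54 and 60.5 ± 2.43 CPM. The guidance list had adjusted p = 0.00487 by camera and adjusted p = 0.149 with an estimated correlation, and missed the threshold without young sample 1 at 0.0726 and without old sample 3 at 0.0652. The VEGF, angiopoietin and adrenomedullin list had 23 of 31 members positive and a median of 0.49. Its member Ptprb, a phosphatase that acts on the angiopoietin receptor, had 669 ± 77.4 and 1140 ± 259 CPM. That list had adjusted p = 0.0240 by camera, adjusted p = 0.259 with an estimated correlation, 0.0581 with library size only and 0.149 with 1 surrogate variable. It also missed the threshold without young sample 2 (0.0820), young sample 3 (0.0638) or old sample 1 (0.233).

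Extracellular matrix genes fell as a list by camera (adjusted p = 0.00346, and adjusted p = 0.282 with an estimated correlation), with 21 of 34 members negative and a median of −0.29. The score went from 8.01 ± 0.06 to 7.63 ± 0.13. Adjusted over the list alone, edgeR passed 6 members, all lower: Col1a2, Sparc, Col1a1, Col3a1, Postn and Lum. Col1a1 (chromosome 11, 94936224 to 94953042, plus strand) and Col1a2 (chromosome 6, 4504814 to 4541544, plus strand), the chains of type I collagen, went from 1532 ± 389 to 545 ± 153 CPM and from 1983 ± 525 to 667 ± 93.5 CPM. Their log2 fold changes were −1.49 (SE 0.27) and −1.57 (SE 0.23). Col3a1, the chain of type III collagen, went from 347 ± 102 to 135 ± 12.6 CPM. Sparc (chromosome 11, 55394500 to 55423183, minus strand), a collagen-binding matrix glycoprotein, went from 2548 ± 134 to 1206 ± 152 CPM, a log2 fold change of −1.08 (SE 0.16), with adjusted p = 0.016 over all genes in DESeq2, 0.048 in limma-voom and 0.235 in edgeR. The fibrillar collagen genes Col5a1 and Col5a2 did not pass, with adjusted p = 0.169 and 0.207 over the list alone. The matrix list missed the threshold without young sample 1 (0.0518), without old sample 2 (0.161) and when members shared between lists were left out (0.299).

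Meningeal fibroblast markers fell as a list, with 13 of 18 members negative, a median of −0.59 and a score of 7.01 ± 0.19 in young and 6.43 ± 0.16 in old cells. The 3 collagen genes belong to this list too. Of the other members, Serpinf1, which encodes a secreted serpin, went from 626 ± 216 to 323 ± 30.2 CPM, Mfap4, a microfibril-associated protein, from 1113 ± 270 to 492 ± 201 CPM, and Lum, a small proteoglycan, from 160 ± 39.4 to 71.0 ± 14.2 CPM. These 3 and the collagens passed adjusted over the list alone in edgeR. Dcn, which encodes decorin, had 664 ± 36.9 and 528 ± 211 CPM, and Ptgds, which encodes a prostaglandin synthase of the meninges, had 241 ± 48.1 and 923 ± 814 CPM. Camera gave adjusted p = 1.5e-05, adjusted p = 0.259 with an estimated correlation and 0.118 when members shared between lists were left out.

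**Figure D2:**
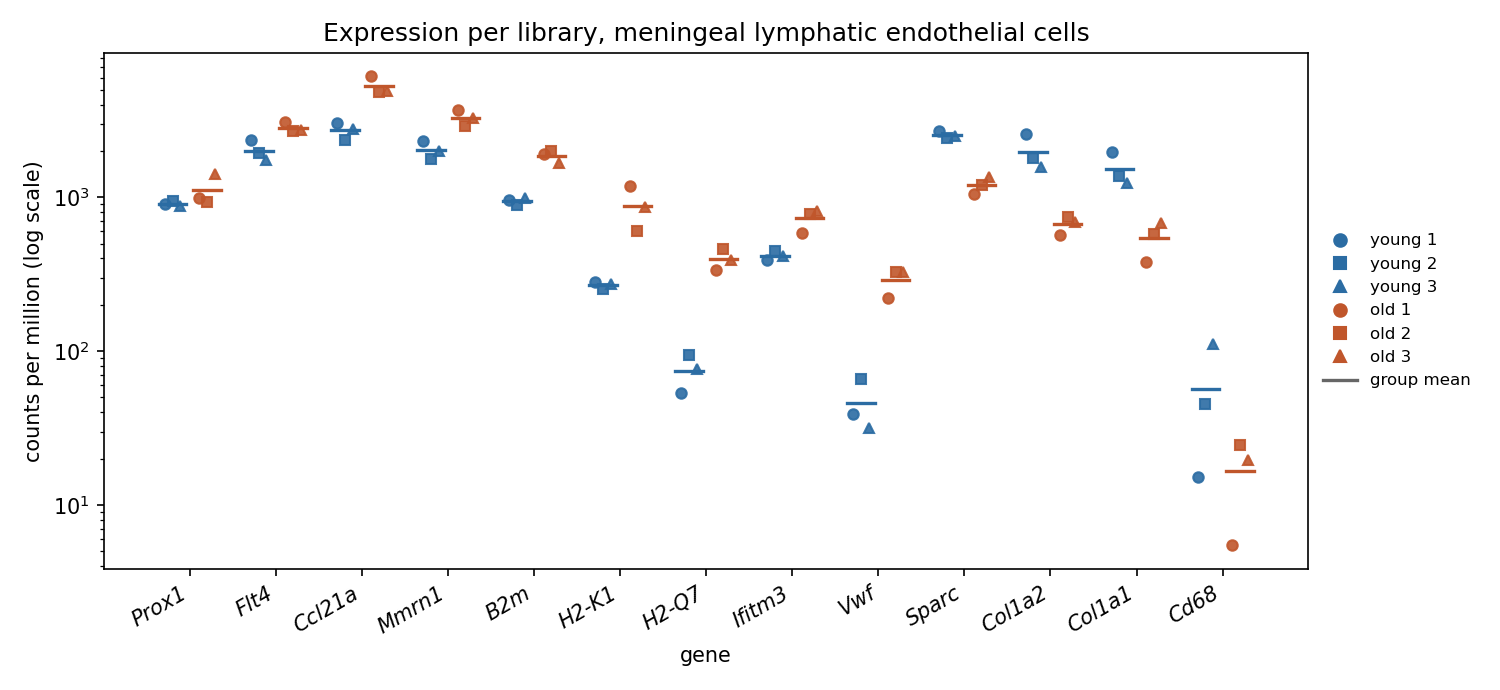
CPM (estimated counts scaled to library size) of 13 genes in each of the 3 young and 3 old samples, on a log axis; each point is a sample and each line is the group mean. B2m, H2-K1, H2-Q7, Ifitm3, Ccl21a and Mmrn1 are higher in every old sample than in every young sample, Col1a1, Col1a2 and Sparc are lower, and Cd68 varies widely among the young samples.

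Markers of other cell types moved in both directions. Macrophage and microglia markers fell as a list, with all 19 members negative and a median of −1.52, but the samples varied widely: the score was 3.52, 6.74 and 7.03 in the young samples and 3.04, 5.56 and 4.48 in the old samples. Cd68, a lysosomal protein of macrophages, had 57.1 ± 48.6 and 16.5 ± 9.85 CPM, and Fcgr3, an Fc receptor, had 70.8 ± 49.1 and 15.9 ± 17.4 CPM. No member passed adjusted over the list alone. Camera gave adjusted p = 0.000107, adjusted p = 0.559 with an estimated correlation, and 0.0638 without young sample 3. Pericyte and smooth muscle markers rose as a list, with 12 of 15 members positive and a median of 0.69. Abcc9, a potassium channel subunit of pericytes, went from 49.3 ± 11.4 to 129 ± 28.5 CPM and passed adjusted over the list alone at edgeR adjusted p = 0.046. Myh11, the smooth muscle myosin, passed likewise at 0.046 but rested on old sample 1, with 668 CPM against 67.8 and 65.8 CPM in the other old samples and 28.4 ± 9.01 CPM in young cells. The pericyte list had adjusted p = 0.00787 by camera and adjusted p = 0.263 with an estimated correlation, and missed the threshold without young sample 2 (0.0508) and without old sample 1 (0.0916).

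Blood endothelial markers rose as a list with 11 of 18 members positive and a median of 0.27. Vwf (chromosome 6, 125546774 to 125686679, plus strand), which encodes von Willebrand factor, went from 45.7 ± 18.2 to 291 ± 61.1 CPM, a log2 fold change of 2.67 (SE 0.37), at edgeR adjusted p = 0.0011 over the list alone and 0.235 over all genes, against DESeq2 adjusted p = 2.9e-07 over all genes. Abcb1a, the drug efflux pump of brain endothelium, went from 32.0 ± 16.4 to 118 ± 31.6 CPM and passed adjusted over the list alone at 0.034. The list had adjusted p = 0.0231 by camera, adjusted p = 0.496 with an estimated correlation and 0.288 without Vwf. It missed the threshold without young sample 1 (0.156), old sample 2 (0.226) or old sample 3 (0.157). The NF-kB and inflammatory mediator list had 18 of 27 members positive and a median of 0.30. Its members with the smallest p were Lcn2, an iron-sequestering secreted protein, with 46.2 ± 29.4 and 123.1 ± 10.05 CPM, and Selp, the adhesion molecule P-selectin, with 17.3 ± 1.81 and 73.7 ± 50.1 CPM. That list had adjusted p = 0.0296 by camera, adjusted p = 0.496 with an estimated correlation, 0.109 with a minimum mean of 50 counts, and 0.576, 0.226 and 0.285 without young sample 1, old sample 2 and old sample 3. Cytosolic ribosomal protein genes had 23 of 28 members positive and a median of 0.34. Rpl18 had 76.1 ± 18.6 and 117 ± 20.7 CPM. The ribosomal list had adjusted p = 0.0102 by camera, adjusted p = 0.496 with an estimated correlation, 0.0578 with library size only, 0.0638 without young sample 3 and 0.211 without old sample 1.

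**Figure D3:**
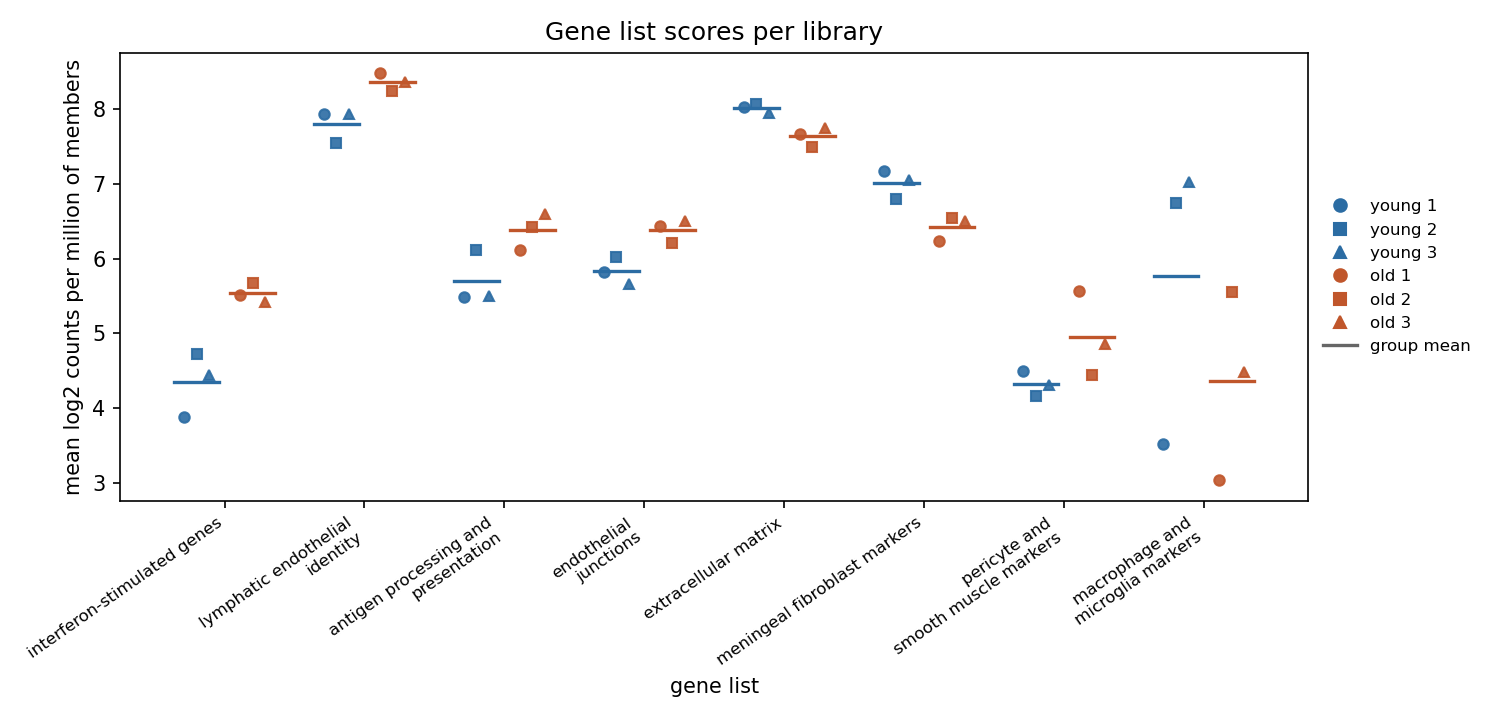
Mean log2 CPM of the members of 8 lists in each of the 3 young and 3 old samples; each point is a sample and each line is the group mean. Interferon-stimulated genes score 4.35 ± 0.43 in young and 5.54 ± 0.13 in old samples, and the macrophage score is 3.52 in young sample 1 and 6.74 and 7.03 in the other young samples.

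The other 20 lists were not called by camera, with adjusted p from 0.219 to 0.854. Among lists for other cell types, lymphocyte and plasma cell markers had adjusted p = 0.319 and a median of 0.42, granulocyte and mast cell markers 0.319, erythroid and platelet markers 0.382, Schwann cell markers 0.671, choroid plexus and epithelial markers 0.714, pineal markers 0.730 and neuron, astrocyte and oligodendrocyte markers 0.854. The lymphocyte list scored 0.82, 2.27 and 1.06 in the young samples and 0.76, 3.23 and 2.64 in the old samples, and was called higher without young sample 2 (0.0214), without old sample 1 (0.0229) and with no filter (0.0259). Without old sample 1 the granulocyte (0.0161), erythroid (0.00875) and Schwann cell (0.0161) lists were also called higher, as was the granulocyte list without young sample 2 (0.0416). The immunoglobulin light chain Igkc passed adjusted over its list alone at edgeR adjusted p = 0.032, at 14.5, 637 and 497 CPM in old samples 1, 2 and 3 and 2.64 ± 2.96 CPM in young cells. Among signalling and stress lists, integrins and cell-matrix adhesion had adjusted p = 0.319, TGF-beta, BMP and Notch signalling 0.338, cell cycle 0.382, endoplasmic reticulum stress 0.440, the immediate-early and dissociation response 0.580, endocytosis and caveolae 0.714, and senescence and p53 response 0.787. Among metabolic lists, mitochondrially encoded messenger RNAs had adjusted p = 0.219 (called higher at 0.0488 by limma-voom and 0.0135 with sample weights), fatty acid uptake and oxidation 0.440, cholesterol synthesis 0.464, nuclear-encoded oxidative phosphorylation 0.714, phospholipid metabolism 0.714 and glycolysis 0.838. The median, the mean and the direction of the test differed in sign for 5 of these lists: the immediate-early, oxidative phosphorylation, choroid plexus, glycolysis and neuron lists.

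Some abundant genes called by DESeq2 were named only after their values were seen. Of the 130 genes that DESeq2 called, 40 had a mean of at least 50 CPM and groups that did not overlap, of which 37 had a symbol, 27 higher and 10 lower in old cells. Non-overlap held for 1848 of the genes tested, or 12.005%, where chance gives 10%. Lower in old cells were Prkcd, a protein kinase C, at 117 ± 43.7 and 21.3 ± 5.23 CPM, Tenm3, a teneurin adhesion protein, at 134 ± 58.4 and 17.5 ± 8.06 CPM, and Slc7a8, an amino acid transporter. The log2 fold change of Slc7a8 was −2.69. Gpr182, an endothelial receptor that binds chemokines, was higher at 48.17 ± 16.01 and 182 ± 73.5 CPM, as was Mcam, the adhesion molecule CD146, with a log2 fold change of 2.27. Ifi204, with a log2 fold change of 2.34, and Iigp1, with 1.17, have near-identical copies that make their estimates uncertain. DESeq2 calls need care here, since 98 of its 150 calls were false on counts simulated for these 15394 genes, against 2 of 20 for edgeR. Those counts were drawn once and took their spread from edgeR, which may favour edgeR in this comparison. Without single samples DESeq2 called from 112 genes, without young sample 3, to 563 genes, without old sample 2, and shared 62 and 112 of them with the 130.

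Genes with no count in any sample of a group were few. There were 29 tested genes at 0 in all old samples and 9 at 0 in all young samples. Old samples 1, 2 and 3 had a count in 17074, 17995 and 17472 genes, fewer than the 18086, 18811 and 18949 in young samples 1, 2 and 3. Gatad2b, a subunit of a chromatin remodelling complex, had 34.4 ± 18.4 CPM in young cells and 0 in old cells, which made it at least 175-fold lower against a floor of 3 counts per sample. Rsc1a1, a regulator of glucose transport, was at least 129-fold lower by the same floor. These bounds cover counting error only, not the spread between samples or the way Salmon assigned reads to genes. They were the largest among genes called by DESeq2 with a group at 0. EdgeR called neither gene over all genes, with adjusted p = 0.235 for Gatad2b and 0.300 for Rsc1a1. A library with 0 counts was present in 23.1% of the genes DESeq2 called and in 15.1% of the genes tested.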

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

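Alternatives chosen only after the data were seen were the minimum mean of 500 counts, the edgeR likelihood ratio test, lists without shared members, and each DESeq2 alternative other than its planned run. Over the named genes, 1045 values under alternatives kept direction and side of the threshold, 67 passed it and 9 reversed, and for lists 551 kept both, 56 lost a call, 9 gained a call and 36 reversed, all 36 in lists that were not called. The interferon list was called in all 14 settings and without each sample in turn, at adjusted p of at most 0.0443. Over the 14 settings, each with all 6 samples, the adjusted p ran from 2.7e-12 to 0.149 for lymphatic identity, 1.1e-06 to 0.149 for antigen presentation, 3.8e-06 to 0.149 for junctions, 3.5e-09 to 0.259 for fibroblasts, 7.5e-07 to 0.601 for macrophages, 5.8e-05 to 0.299 for matrix, 0.00255 to 0.149 for guidance, 0.00458 to 0.344 for pericytes, 0.00336 to 0.496 for ribosomal genes, 0.00472 to 0.508 for blood endothelium, 0.00947 to 0.259 for VEGF and 0.00472 to 0.530 for NF-kB. No 2-fold change was recovered by edgeR on counts simulated at the depth and spread of these samples, so a count of 0 does not show that genes did not differ.

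Beside 0 genes by edgeR, DESeq2 called 130 (66 higher, 64 lower), the likelihood ratio test 76 (32, 44), limma-voom 3 (2, 1), limma-voom with sample weights 5 (4, 1) and a minimum mean of 500 counts 7 (4, 3), the last with fewer genes tested. Other settings called 0, and leaving out 1 sample 0 to 1 genes, 0 to 1 of them higher, where the 1 gene without old sample 1 was Igkv10-96. DESeq2 called 294 genes without a filter, 334 with the replicate block and 112 to 563 without 1 sample. Beside 13 lists, camera with an estimated correlation called 1. Only the correlation setting was changed from the main test, so the other 12 calls depend on the use of a preset. With an estimated correlation, camera also takes its p from the few residual degrees of freedom. Whether the value of 0.01 or those degrees of freedom made the difference was not tested. Fry also called 1, for a reason that was not tested. With the replicate block 0 genes and the same 13 lists were called. Same-numbered samples correlated at 0.08, 0.05 and −0.01 in their deviations from the group means, and young sample 3 correlated best with old sample 2, so the numbers were not taken as pairs.

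Ptprc turned from −0.07 to a log2 fold change of 1.10 by limma-voom, 0.43 with sample weights, 0.82 with the replicate block and 0.14 with 1 surrogate variable, and ran from −0.64 to 0.50 without 1 sample. The Pdpn log2 fold change ran from −0.053 to 0.63 without 1 sample. The test direction turned in uncalled lists, whose adjusted p there was, for library size only, 0.908 (endocytosis) and 0.998 (neuron); for no filter 0.798 (senescence); for a minimum mean of 50 counts 0.894 (neuron). With a minimum mean of 500 counts it was 0.898 (immediate-early, cholesterol and phospholipid), 0.453 (glycolysis) and 0.967 (endocytosis). With 1 surrogate variable it was 0.971 (endoplasmic reticulum stress and pineal), 0.953 (senescence) and 0.915 (neuron). Without the member with the smallest p it was 0.849 (glycolysis), 0.928 (neuron) and 0.784 (choroid plexus). Without 1 sample, lists that turned in at least 1 fit had adjusted p of 0.0972 to 0.862 (immediate-early), 0.0672 to 0.998 (endoplasmic reticulum stress), 0.630 to 0.998 (glycolysis), 0.116 to 0.786 (cholesterol), 0.526 to 0.915 (phospholipid), 0.0623 to 0.950 (cell cycle), 0.608 to 0.998 (senescence), 0.0161 to 0.781 (granulocyte), 0.00875 to 0.970 (erythroid), 0.553 to 0.938 (neuron), 0.218 to 0.938 (choroid plexus), 0.0161 to 0.980 (Schwann) and 0.138 to 0.998 (pineal). The cause of these turns was not tested.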

Other observations

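Tests chosen only after the result was seen were the splits of the samples for the edgeR count, the leukocyte scores, the fibroblast and pericyte scores, and the imprinted genes against fibroblast markers. Imprinted genes, which are expressed from 1 parental copy and regulate growth, drew attention through H19, Rian and Zim1. H19, a noncoding RNA next to Igf2, had 1025 ± 557 CPM in young and 500 ± 110 CPM in old cells. Rian, a noncoding RNA of the Dlk1 and Meg3 region, had 42.6 ± 13.9 and 3.11 ± 2.44 CPM, and Zim1, a zinc finger gene, had 28.4 ± 7.52 and 4.97 ± 2.07 CPM. A list of 15 other imprinted genes, written after those 3 were noticed and before its own result was seen, had 13 negative members and a median log2 fold change of −0.53. It holds chromosomal neighbours of those 3: Igf2 near H19, Peg3 near Zim1, and Meg3 and Mirg near Rian. Its result is therefore not independent of the genes that prompted it. No imprinted gene passed over all genes in edgeR, while DESeq2 gave Rian adjusted p = 0.0040 and Zim1 adjusted p = 0.0318. The 4 members of the list with the smallest p were Igf2, Igf2r, Peg3 and Meg3. Igf2, a fetal growth factor, had 1878 ± 262 and 1252 ± 278 CPM, Meg3 had 79.8 ± 14.4 and 24.4 ± 16.7 CPM, Peg3 had 290 ± 170 and 110 ± 62.4 CPM, and Igf2r, the receptor that clears Igf2, had 147 ± 13.6 and 79.5 ± 18.8 CPM. Mirg and Nnat were positive, with log2 fold changes of 2.36 and 1.05, and Mest had −0.03. Igf2 is also in the list of meningeal fibroblast markers and was left out of the score, though not out of the list test. The score over the other 14 members was 5.08 ± 0.24 in young and 4.62 ± 0.73 in old samples, and the ages overlapped. By camera the list had adjusted p = 0.00428 over the 3 lists added after the data were seen, and adjusted p = 0.0380 with an estimated correlation.

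The lower imprinted genes may reflect age or fewer fibroblasts in the old sorts, and the median of −0.53 for the list without H19, Rian and Zim1 does not tell these apart. The gate kept CD31-positive cells, and the share of fibroblasts that passed it was not measured. The score of imprinted genes minus that of fibroblast markers other than collagens differed by −0.055 between old and young samples, with an SD of 0.36 in young and 0.58 in old samples. By the criterion first written this would have counted for fewer fibroblasts. The criterion was changed to undecided after the value was seen, because 2 SD of the difference exceed the difference in the imprinted score itself, −0.46. Both explanations stay open, as does the untested source of the mice.

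The higher interferon and antigen presentation lists could come from more leukocytes in the old sorts, although the gate removed CD45-positive cells, and the data leave this open. The score over 41 leukocyte markers was 3.35 ± 1.44 in young and 3.02 ± 1.33 in old samples, so that 7 of the 9 pairs with a higher interferon and a lower leukocyte score in the old sample decide nothing, although the criterion first written for them counted against leukocytes. The leukocyte lists also went apart, with median log2 fold changes of −1.52 for macrophages and 0.42 for lymphocytes, whose list was called higher without old sample 1 (0.0229) or young sample 2 (0.0214). Reads shared between near-identical copies are argued against by the 37 members without such a copy, which had a median log2 fold change of 0.82, with 31 positive and an interquartile range of 0.18 to 1.52. Age itself and the source of the mice, which the labels do not give per sample, remain open and untested.

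Lower collagens beside higher lymphatic genes may reflect fewer fibroblasts in the old sorts, although the gate kept cells positive for the endothelial protein CD31. The score of Col1a1, Col1a2 and Col3a1 minus that of the other fibroblast markers differed by −1.06, but these collagens were singled out because they were low in old cells, so the difference decides nothing, although the criterion first written counted it against fewer fibroblasts, and the other markers differed too, by −0.40. A larger share of lymphatic endothelial cells would lower the markers of other cell types alike. The fibroblast score minus the pericyte and smooth muscle score went from 2.68 ± 0.05 to 1.47 ± 0.73, a difference of −1.21. It was 0.67, 2.09 and 1.64 in old samples 1, 2 and 3. The criterion written for this difference counted it against that share as the whole cause. The fibroblast score includes the same collagens and the difference was not computed without them, so it decides nothing. The pericyte and smooth muscle score itself went from 4.32 ± 0.17 to 4.96 ± 0.56. A larger share of lymphatic endothelial cells alone would lower that score, but the ages overlapped, so this does not decide either. A larger share of lymphatic endothelial cells, fewer fibroblasts, age and the source of the mice remain open.

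The 6 samples can be split into 3 and 3 in 10 ways, which is too few for a share under 0.05. All 10 splits gave as many edgeR calls as the real one, with 0 for the real split and a highest of 0 for the others. For edgeR genes at an unadjusted threshold, 2 splits gave as many, with 856 for the real split and a highest of 869 for the others. DESeq2 gave as many in 2 splits, with 130 for the real split and 239 for the split of young sample 1 with old samples 1 and 3 against the rest. For lists called, 1 split, the real one, gave 13, and the highest of the others gave 11. The interferon list had its smallest adjusted p in 1 split, the real one, at 1.4e-13, against 0.00169 in the next.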
